A study of Mus musculus with 6 samples.

How the data were processed

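Gene expression was measured in mouse CD4+CD25+ regulatory T cells (Treg), the T cell subset that restrains immune responses, from HDAC6 knockout animals and from wild-type controls. HDAC6 is a mostly cytoplasmic deacetylase whose known substrates include tubulin and the chaperone HSP90. Per the labels' protocols, total RNA was purified on columns and amplified and labelled with biotin for 1-colour oligonucleotide arrays. Per the series' design text the cells had been separated magnetically. The labels and the design text gave 3 arrays per genotype, described as independent samples, and a strain for the wild-type group alone. Whether a sample was 1 animal or a pool was not given in the sources used here. No purity, detection call, slide or scan date was used here, so no recorded batch could be tested.

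The authors deposited 1 table of normalized values for all 6 arrays, with 22690 probe sets and 0 missing values. Per the submitters' processing notes the values came from RMA (robust multi-array averaging, which corrects background, normalizes by quantiles and summarizes the probes of a set), with no version given. The deposited values were taken as log2 from their range, and no further normalization was applied. RMA compresses differences of dim and of near-saturated probe sets, so changes at either end of the scale can be understated. The number of arrays limits the precision: the median standard error of a log2 change was 0.10 over probe sets.

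The 64 control probe sets were left out of the tests, which left 22626. Names came from the platform's annotation, updated through its gene IDs, of which those of 20351 probe sets were found in the RefSeq gene table (assembly GRCm38.p6). Of the tested probe sets, 20380 carried 1 gene symbol, 691 several and 1555 none, and genes were named only from the first kind. The build behind the array design was not given in the sources used here, so the RefSeq table served only for names and for which genes neighbour each other.

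Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values are two-sided unless stated. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 12393 genes, and p-values were adjusted again over these genes. Adjusted p-values are over all genes unless probe sets or a list are named. The 4956 genes with more than 1 probe set can give other values from another probe set. Changes are log2 differences, knockout minus wild type, and errors are standard errors (SE) or standard deviations (SD, n = 3).

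The comparisons, the named genes and 28 gene lists were fixed before the data were examined. The named genes were Hdac6, up to 10 genes per direction with the largest change among those past the threshold and without overlap between genotypes (filled up to 10 by smallest p where fewer passed), up to 4 members of each list with the smallest p, and a set of Treg and chaperone genes given in every case. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. Beside the count over all genes, the count of members past the threshold when adjusted over the list alone is given. The X-linked neighbours of Hdac6 were compared with 10000 random gene lists matched on mean level in 20 bins. The alternatives were a replicate block, quantile normalization, median centring, eBayes with trend and robust settings, array weights, filters on dim probe sets (the upper 60% by mean, or a mean log2 value of at least 6), an unmoderated test, other rules for a gene's probe set, a looser threshold of 0.1, an added 1.5-fold minimum, and leaving out each array in turn. A sex term was not run, because all 6 arrays showed the male pattern of sex-specific transcripts. Xist read at most 4.10 and the Y-linked Eif2s3y at least 8.66 in every array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

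The fit was tested on simulated data for the knockout against wild type comparison over 22626 probe sets, in 5 runs of 200 changed probe sets each. It recovered 24.8% of changes of 0.5 on the log2 scale, 83.3% of changes of 1 and 99.1% of changes of 2. Of its 729 calls, 39 (5.35%) were false. The simulated errors were drawn independently for each probe set, with spreads from the distribution that limma fitted to these arrays. Real genes vary together, so this share does not measure the false calls in the real data.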

Results

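Transcript levels of CD4+CD25+ Treg from HDAC6 knockout and wild-type mice were measured on 6 arrays, 3 per genotype, to ask how loss of this deacetylase alters the cells; the study's title places HDAC6 beside HSP90 in Foxp3+ Treg function. The arrays were alike in scale, with medians from 6.22 to 6.27 on the log2 scale. Pearson's r across probe sets, which are not independent replicates, was 0.994 to 0.996 for the 6 pairs within a genotype and 0.992 to 0.995 for the 9 pairs between genotypes. The first principal component held 35.4% of the variance and placed the knockout arrays at -11.0, -15.0 and -18.8 and the wild-type arrays at 22.4, 17.9 and 4.42. The second held 22.5% and placed the replicate 1 arrays of both genotypes at 16.2, and the others from -15.1 to 3.35.

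Hdac6 itself was lower in every knockout array than in every wild-type array. Its probe set read 7.54, 7.86 and 7.64 in the knockout and 8.54, 8.23 and 8.42 in wild type, a log2 difference of -0.71 (SE 0.11, 95% interval -0.98 to -0.44), or 1.64-fold lower. Limma's adjusted p was 0.0875 over probe sets, so the difference did not pass the threshold. The gene had 1 probe set of its own. Where it lies relative to the deleted part was not given in the sources used here, so a residual signal neither checks nor contradicts the labels.

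Among genes past the threshold the immunoglobulin transcripts Igk and Igha rose most in the knockout Treg preparations, and the genes that fell included the chemokine receptor Cxcr6 and the Wnt secretion factor Wls. Igk, the kappa light chain locus, rose by 2.20 (SE 0.20, adjusted p = 0.0143), with 3 of its 4 probe sets higher and the other at -0.05. Probe sets that name the kappa constant gene Igkc among others differed by 0.24, 0.24 and 0.31 and did not pass. Igha, the constant region of IgA, rose by 1.81 (SE 0.14, adjusted p = 0.0105). It reached a mean of 14.30 (SD 0.05, n = 3), near the top of the measured range, where a rise can be understated. Its other probe sets rose by 2.28 and 2.79. Casp1, the protease that matures interleukin-1β, rose by 0.83 (SE 0.07), from 7.88 to 8.71. Cxcr6, a receptor that guides T cells into tissues, fell by 1.05 (SE 0.12, adjusted p = 0.0310), and Wls fell by 1.29 (SE 0.07, adjusted p = 0.00578), with all 3 of its probe sets lower.

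The other genes that rose were Khdc1a (1.44, SE 0.14), Ttn, which encodes the muscle protein titin (1.16, SE 0.13), the acyltransferase gene Lclat1 (0.91, SE 0.08) and the aminopeptidase gene Aopep (0.62, SE 0.07). The lists of risers were filled with Nfil3, a transcription factor of lymphocyte development (0.70, adjusted p = 0.0564), Naip5, a sensor of bacterial flagellin (1.48, adjusted p = 0.0564) and Rsrp1 (0.56, adjusted p = 0.0645), none of which passed at the gene level. A dimmer probe set of Rsrp1 rose by 1.38 (adjusted p = 0.0148 over probe sets). Tmem87a fell by 2.69 (SE 0.24), from 9.17 to 6.48, the largest fall among genes past the threshold. Pstpip2, a regulator of the actin cytoskeleton, fell by 1.66, the secreted netrin Ntn4 by 1.63 and the alcohol dehydrogenase Adh1 by 1.39. The interferon-induced guanylate-binding protein Gbp2b fell by 1.39 and the endosomal protein Ehd3 by 1.20. The histidine-degrading enzyme Hal fell by 1.18 and the tRNA-editing enzyme subunit Adat2 by 0.95. Some of these genes were dim in the genotype where they were lower. Khdc1a (3.57) and Ttn (4.59) in wild type and Hal (4.04) and Ntn4 (4.39) in the knockout lay near the arrays' lower quartiles (4.14 to 4.25). Without detection calls their expression in these cells is not established.

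**Figure D1:**
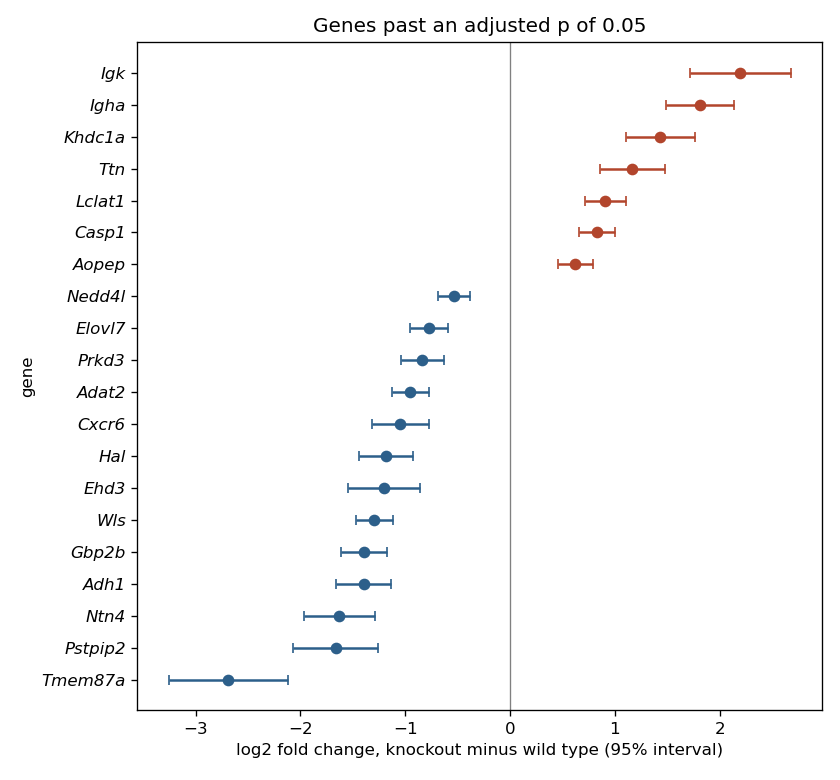
Log2 fold change (knockout minus wild type, horizontal axis) of the 20 genes past an adjusted p of 0.05, 1 gene per row, with 95% intervals as bars (3 arrays per genotype). The 7 genes that rose lie right of 0, led by Igk at 2.20, and the 13 that fell lie left of it, with Tmem87a lowest at -2.69. Each gene is shown by its brightest probe set, and other probe sets of Igha rose by 2.28 and 2.79.

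Over all, 20 of 12393 genes passed the threshold, 7 higher and 13 lower in the knockout. Over probe sets, 44 of 22626 passed, 18 higher and 26 lower, of which 42 differed by at least 1.5-fold. Immunoglobulin probe sets made up 7 of the 18 that rose and 0 of the 26 that fell. A further 3 of the 18 and 1 of the 26 carried no gene symbol and were not classed, among them those with the 2 largest rises, 3.24 and 3.06. Over all probe sets 2403 had an unadjusted p under 0.05. For 3883 probe sets (17.2%) the genotypes did not overlap, against 10% by chance. Probe sets of 1 gene could differ: for Il7r, the receptor for the survival cytokine interleukin-7, the dimmer probe set fell by 1.26, and the brighter one differed by -0.57 and did not pass. Of the 3 probe sets of Id2, a transcriptional regulator of innate-like and effector lymphocytes, 2 fell, by 0.83 and 0.64, and the brightest differed by -0.78 and did not pass. Others went against their gene's brightest probe set. A probe set of Sypl fell by 0.89 and 1 of Actb rose by 0.66, while the brightest differed by 0.08 and -0.01. Il7r, Id2, Sypl and Actb at the probe-set level were chosen after their values were seen. The counts moved with the array left out: 5 probe sets and 3 genes passed without knockout replicate 2, 11 and 3 without wild type replicate 2, 20 and 8 without knockout replicate 1, 31 and 14 without knockout replicate 3, 37 and 19 without wild type replicate 1, and 51 and 27 without wild type replicate 3. An unmoderated test called 0 of either, with 2239 probe sets and 1353 genes at an unadjusted p under 0.05, and eBayes with trend and robust settings called 147 and 83.

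**Figure D2:**
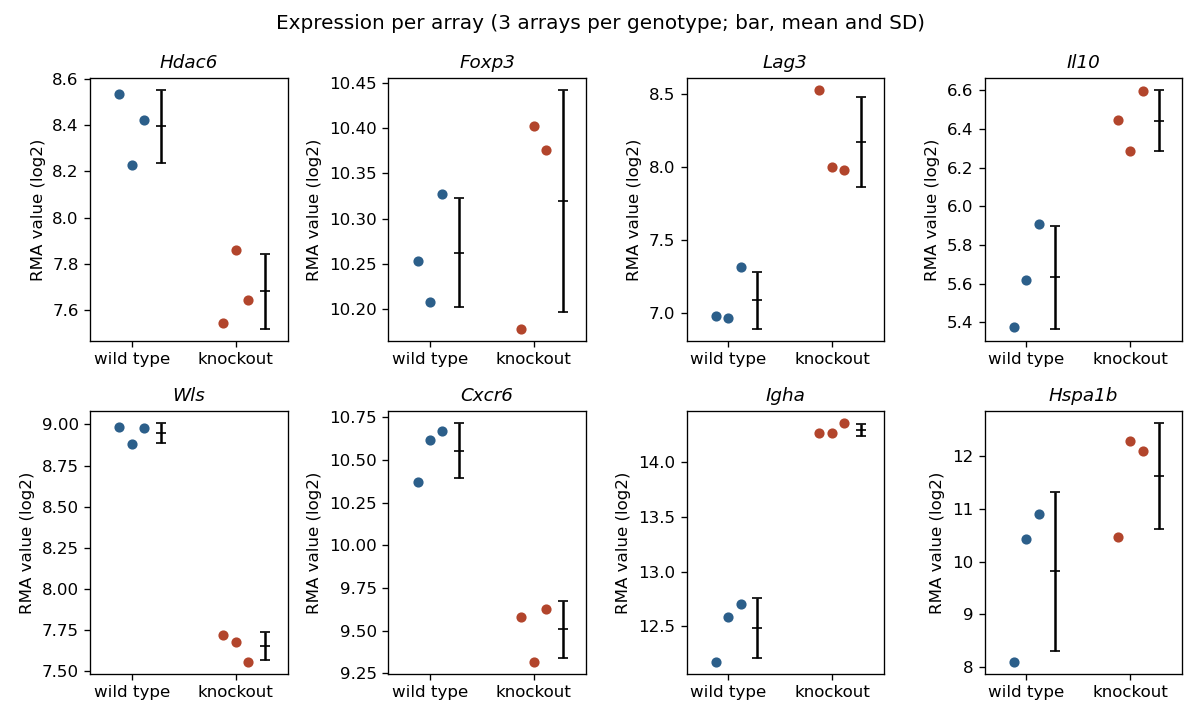
RMA values (log2, vertical axis, with its own range in each panel) of 8 genes in the 3 wild-type and 3 knockout arrays, 1 point per array, with the mean and SD beside them. Hdac6, Wls and Cxcr6 were lower and Lag3, Il10 and Igha higher in every knockout array, Foxp3 overlapped between genotypes (10.26 and 10.32), and Hspa1b ranged from 8.10 to 10.91 in wild type and from 10.47 to 12.28 in the knockout.

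Treg signature genes were higher as a set in the knockout (camera adjusted p = 0.000395; adjusted p = 0.465 with an estimated correlation), with 19 of 25 measured members higher and 6 lower. Foxp3, the transcription factor that defines these cells, averaged 10.32 (SD 0.12, n = 3) in the knockout and 10.26 (SD 0.06, n = 3) in wild type, a difference of 0.06 (SE 0.08, adjusted p = 0.853). Il2ra, the interleukin-2 receptor chain CD25 by which the cells were separated, differed by 0.01 (SE 0.12), the inhibitory receptor Ctla4 by 0.16 (SE 0.10) and the costimulatory receptor Icos by 0.18 (SE 0.13), none past the threshold. Leaving out 1 array, Foxp3 ranged from 0.02 to 0.13 (without knockout replicates 2 and 1), Il2ra from -0.05 to 0.12 (without knockout replicate 2 and wild type replicate 1), and Ctla4 and Icos dropped to 0.09 and 0.06 without wild type replicate 3. Of the list's members 0 passed over all genes, and 6 rose and 1 fell when adjusted over the list alone. Those that rose included Nt5e and Entpd1, the ectoenzymes CD73 and CD39 that turn extracellular ATP into adenosine (0.76 and 0.44), the TNF receptor Tnfrsf1b (0.47) and Nrp1 (0.38), and the 1 that fell was Gpr83 (-0.47).

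Suppressor and effector Treg genes were higher as a set in the knockout (camera adjusted p = 0.000106; adjusted p = 0.465 with an estimated correlation). Cst7, a protease inhibitor of cytotoxic cells, differed by 0.99 (SE 0.13, adjusted p = 0.0645), the inhibitory receptor Lag3 by 1.08 (SE 0.17, adjusted p = 0.0862), the suppressive cytokine Il10 by 0.81 (SE 0.15, adjusted p = 0.112) and the transcription factor Maf by 0.33 (SE 0.08, adjusted p = 0.192), each without overlap between genotypes. Of 23 measured members, 18 were higher and 5 lower, 0 passed over all genes and 5 rose when adjusted over the list alone.

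The heat shock response genes, targets of the stress factor HSF1, were higher as a set (camera adjusted p = 0.00155; adjusted p = 0.734 with an estimated correlation). Of 24 measured heat shock genes, 18 were higher and 6 lower, 0 passed over all genes, and 4 rose when adjusted over the list alone: the HSP40 genes Dnajb1 (0.86) and Dnajb4 (0.64), the co-chaperone Bag3 (0.60) and the small heat shock protein Hspb1 (0.80). The list missed the threshold without knockout replicate 1 (0.0603) or wild type replicate 3 (0.107). The inducible HSP70 genes Hspa1a and Hspa1b differed by 2.30 (SE 1.04, adjusted p = 0.473) and 1.81 (SE 0.78, adjusted p = 0.458), and by 1.27 and 0.95 without wild type replicate 1. With the replicate number as a block limma's adjusted p for Hspa1a was 0.0404, the lowest among the alternatives. Hspa1b read 10.47, 12.28 and 12.10 in the knockout and 8.10, 10.42 and 10.91 in wild type. Hsp90aa1, the inducible HSP90, differed by 0.22 (SE 0.11, adjusted p = 0.537). Hsp90ab1 and Hsf1 had no probe set of their own. Of 24 HSP90 family and co-chaperone genes, among them Ppp5c (0.29) and Cacybp (0.24, or 0.16 without wild type replicate 3), 16 were higher and 8 lower and 0 passed by either adjustment. As a set they did not pass (camera adjusted p = 0.210), except without wild type replicate 2 (0.00346), and the difference between the heat shock and HSP90 lists was not tested.

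Genes tied to other known roles of HDAC6 did not pass as sets. Of 38 ubiquitin, aggresome and proteasome genes 20 were higher and 18 lower (median 0.00, mean -0.01, camera adjusted p = 0.835), with Ubqln2 at -0.12 (-0.07 without wild type replicate 3) and Psmb6 at -0.08. Of 22 tubulins and cytoskeletal partners 10 were higher and 12 lower (camera adjusted p = 0.460), with the tubulin genes Tubb2a at -0.56 and Tuba1a at -0.29. Of 12 other histone deacetylases and sirtuins 4 were higher and 8 lower (camera adjusted p = 0.174), with Sirt1 at -0.36 (-0.20 without knockout replicate 3) and Hdac5 at -0.22. In all 3 lists 0 members passed by either adjustment.

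Interferon response genes showed the lowest set p. Of 34 measured members 30 were higher and 4 lower, 0 passed over all genes, and 8 rose when adjusted over the list alone, including the antiviral genes Oasl2 (1.57, SE 0.34), Rsad2 (1.15, SE 0.25) and Mx1 (0.74, SE 0.17). The camera adjusted p was 4.41e-10 (adjusted p = 0.734 with an estimated correlation). Relative to the wild-type mean the list averaged 0.68 in knockout replicate 1 and 0.22 and 0.23 in the other knockout arrays. Activation-induced and NF-κB target genes were also higher as a set: 16 of 21 were higher and 5 lower, with Egr2 at 0.46 and Cd83 at 0.29, and 0 passed by either adjustment (camera adjusted p = 0.000791; adjusted p = 0.465 with an estimated correlation). Of 20 immediate early genes, which respond within minutes to stimulation or cell handling, 13 were higher and 7 lower, and the growth arrest gene Gadd45a (-0.51) fell when adjusted over the list alone. For that list the median was 0.05 and the mean 0.02 while camera's direction was down (adjusted p = 0.989).

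Cell division genes were higher in 33 and lower in 4 of 37 measured members, with the replication helicase subunit Mcm6 at 0.39 (SE 0.13) and the mitotic kinase Aurka at 0.32 (SE 0.14), or 0.20 without wild type replicate 3 and 0.21 without knockout replicate 1. By either adjustment 0 passed, with limma's adjusted p at 0.337 for Mcm6, and the set's camera adjusted p was 3.71e-05 (adjusted p = 0.734 with an estimated correlation). The set missed the threshold without knockout replicate 1 (0.0640) or wild type replicate 3 (0.293). Unfolded protein response genes were higher in 16 and lower in 10 of 26 members, and 3 rose when adjusted over the list alone. These were Edem1 (0.67) and Manf (0.45), which act in the endoplasmic reticulum, and Xbp1 (0.40), a factor of secretory cells. Member changes ranged from -0.73 to 0.67, so the largest was a fall, which passed by neither adjustment. The set's camera adjusted p was 0.0213 (adjusted p = 0.734 with an estimated correlation), and it missed the threshold without knockout replicate 1 (0.377), knockout replicate 3 (0.0611), wild type replicate 1 (0.0918) or wild type replicate 3 (0.203). Immunoglobulin transcripts, products of secretory cells, moved the same way.

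Naive and resting T cell genes were lower as a set (camera adjusted p = 0.0391; adjusted p = 0.734 with an estimated correlation). Of 17 measured members 12 were lower and 5 higher, and 0 passed over all genes. Il7r (-0.57), Satb1 (-0.39), a chromatin organizer, and S1pr1 (-0.63), the receptor for lymph node exit, fell when adjusted over the list alone. Member changes ranged from -0.63 to 1.30, so the largest was a rise, which passed by neither adjustment. The set missed the threshold without knockout replicate 1 (0.130), knockout replicate 3 (0.0724), wild type replicate 1 (0.169) or wild type replicate 3 (0.203), and with quantile normalization (0.0656).

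Among chemokine receptors and adhesion molecules members went both ways. Cxcr6 was the 1 member that fell over all genes. When adjusted over the list alone 3 of 21 rose, among them Cxcr5, which guides cells into B cell follicles (0.72), and 3 fell, among them Ccr2, a receptor of inflamed tissue (-0.72) and Cxcr6 (camera adjusted p = 0.810 for the set, median 0.01, mean 0.00). Of 20 helper T cell cytokines and lineage factors 8 were higher and 12 lower; adjusted over the list alone, Il21 (1.30), the follicular helper cytokine, rose, and Il4 (-1.15), the type 2 cytokine, and Rora (-0.41) fell (camera adjusted p = 0.487). T cell receptor signalling genes gave 11 higher and 12 lower of 23, with Nfatc1 at 0.48 and Cd4 at 0.21, and 0 past by either adjustment (median -0.02, mean 0.01, camera adjusted p = 0.998). Of 19 interleukin-2 and STAT5 targets 12 were higher and 7 lower, and the xenobiotic receptor Ahr (0.56) and the signalling inhibitor Socs3 (0.71) rose when adjusted over the list alone (camera adjusted p = 0.211).

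Glycolysis genes were higher in 18 and lower in 3 of 21 members by small amounts, with a median of 0.07. The lactate transporter Slc16a3 (0.42, SE 0.08) rose when adjusted over the list alone, and the pyruvate kinase Pkm was at 0.21. The set's camera adjusted p was 0.0179 (adjusted p = 0.465 with an estimated correlation), and it missed the threshold without knockout replicate 1 (0.130), wild type replicate 2 (0.0636) or wild type replicate 3 (0.107). Of 46 oxidative phosphorylation genes 16 were higher and 30 lower (camera adjusted p = 0.490), with Ndufs1 at -0.14. Of 34 ribosomal protein genes 6 were higher and 28 lower, with Rps15 at -0.15 (camera adjusted p = 0.0569, 0.0434 without wild type replicate 2 and 0.00107 with trend and robust settings, where the alternatives ranged up to 0.734). Among 19 cholesterol synthesis genes 8 were higher and 11 lower, and Stard4, a sterol carrier, fell by 1.20 when adjusted over the list alone, with an adjusted p of 0.0764 over all genes, while a dimmer probe set of it fell by 0.74 and passed over probe sets (camera adjusted p = 0.652 for the set).

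**Figure D3:**
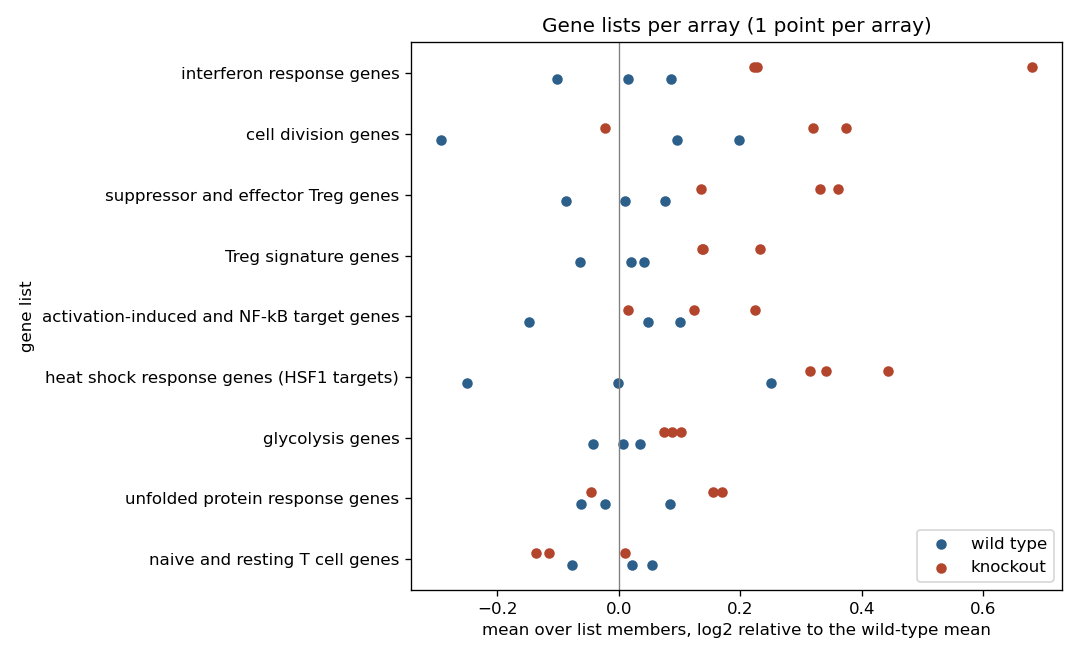
Mean over the members of each of the 9 gene lists past the threshold (vertical axis), in log2 relative to the mean of the wild-type arrays (horizontal axis), 1 point per array. Knockout points lie right of the wild-type points for the interferon, suppressor, Treg signature, heat shock and glycolysis lists, and knockout replicate 1 stands apart at 0.68 for the interferon genes.

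Of the 5 fixed lists of markers of other cell types that a magnetic separation could carry over, 0 passed as a set over the 6 arrays. Plasma cell genes, listed only after part of their values had been seen, were higher in 19 of 20 cases, with a median of 0.29 (camera p = 5.55e-09; p = 0.0829 with an estimated correlation). Of 15 B cell markers 9 were higher and 6 lower (median 0.04, mean -0.13, camera adjusted p = 0.835); adjusted over the list alone, 2 rose, Jchain, which joins secreted IgA and IgM (0.58), and Vpreb3 (0.48), and 2 fell, Ms4a1, which encodes CD20 (-1.13), and Spib (-0.94). Of 26 antigen-presenting and myeloid markers 13 were higher and 13 lower (median 0.01, mean -0.08, camera adjusted p = 0.604), with H2-Eb1 at -0.30 (-0.20 without knockout replicate 1). Of 12 neutrophil markers 6 were higher and 6 lower, with Mmp9 at 0.83, or 0.46 without wild type replicate 1; their median was -0.25 and their mean -0.19 while camera's direction was up (adjusted p = 0.835). Of 16 CD8 T cell and NK cell markers 5 were higher and 11 lower; adjusted over the list alone, Gzmk (0.66) rose and the granzyme Gzma (-1.03) and Cd8b1 (-0.37) fell (camera adjusted p = 0.635, and 0.0325 without wild type replicate 1). Of 12 erythroid and platelet markers 7 were higher and 5 lower, with Gp9 at 0.18 (median 0.03, mean 0.00, camera's direction down, adjusted p = 0.989). Sex-specific transcripts gave 2 higher and 3 lower of 5 (camera adjusted p = 0.460), with Xist, the transcript that silences an X chromosome, at 3.90 and 3.63 and the Y-linked Eif2s3y at 9.12 and 9.56 in knockout and wild type.

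Over the 28 lists, 9 passed at the preset correlation, 8 higher and 1 lower. Other groupings of the 6 arrays, which mix the genotypes, gave 2 to 8 lists at this setting, so the count hardly sets the genotypes apart. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05, and fry's directional test called 0, with 6 at an unadjusted p under 0.05, while its mixed test, for members that change either way, called 12. At the preset correlation the number fell to 4 without knockout replicate 1 and to 4 without wild type replicate 3. Among the 9 called lists the estimated correlation between genes ranged from 0.005 (glycolysis) to 0.80 (cell division), with 0.62 for the interferon list. Where it is far above the preset 0.01, the p-values at the preset correlation overstate the evidence.

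The X-linked neighbours of Hdac6, a list that includes Foxp3, were not found to differ more than other genes. The median absolute log2 difference of 28 measured neighbours was 0.08, against a median of 0.09 (95% range 0.05 to 0.13) over 10000 random lists matched on mean level (two-sided permutation p = 0.627). Of the neighbours 12 were higher and 16 lower, with Wdr13 at -0.25 and the erythroid factor Gata1 at -0.26 (-0.16 without knockout replicate 3), and 0 passed by either adjustment (camera adjusted p = 0.308).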

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

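All alternatives here were planned, except that the direction of a list was defined as the sign of its mean change only after the first results were seen. By that rule 22 of 321 values of lists outside the 9 called ones turned sign; by camera's own direction 39 did, by either rule 57. For the 9 called lists 0 of 153 did by either rule. Signal over background could not be used, because no detection calls were at hand.

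Of the 44 probe sets and 20 genes called, the threshold of 0.1 gave 121 and 71. The replicate block gave 27 probe sets, 19 of them among the 44, and 14 genes, 9 of them among the 20. Same-numbered arrays deviated together with r of 0.22, -0.09 and 0.10. Only number 1 correlated best with its own number, so the numbers were not taken to pair the samples. The replicate 1 arrays of both genotypes also lay at 16.2 on the second principal component (22.5% of the variance). A shift shared by these arrays was therefore not excluded. Trend and robust settings gave 147 probe sets and 83 genes, and moved Hdac6 past the threshold (-0.71, adjusted p = 0.0259, where the other alternatives gave 0.0589 to 0.318). Array weights gave 86 probe sets, a mean log2 value of at least 6 gave 34 genes, the probe set with the highest variance 34 genes, and the unmoderated test 0 and 0. Leaving out 1 array moved 36 of 140 named genes by over 1.5 times, 0 of them past the threshold, and gave 5 to 51 probe sets, 3 to 27 genes and 4 to 10 lists. Lists numbered 0 with camera's estimated correlation and 0 with fry. Array weights also ended the calls of the cell division (0.0519), naive (0.189) and unfolded protein response lists (0.282), the replicate block (0.0649) and the highest-variance probe set (0.0613) that of the unfolded protein response list, and quantile normalization (0.0656) and both filters (0.118 and 0.161) that of the naive list. The cause was not tested for any of these, apart from fewer samples when an array was left out.

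Values that changed sign were outside the calls. Leaving out 1 array, Il2ra ranged from -0.045 to 0.12, Lcn2 from -1.06 to 0.070, and the list means from -0.0186 to 0.00559 (ubiquitin and proteasome), -0.0266 to 0.0438 (chemokine receptors), -0.122 to 0.113 (immediate early), -0.217 to 0.00501 (B cell), -0.169 to 0.0332 (myeloid), -0.410 to 0.225 (neutrophil), -0.198 to 0.0187 (CD8 and NK cell) and -0.0292 to 0.0530 (erythroid). The chemokine receptor mean was 0.00618 with quantile normalization, 0.00211 with median centring and 0.00340 in the upper 60% by mean, and the erythroid mean -0.0140 with quantile normalization. With the mean over probe sets Slc4a1 was 0.033 and the immediate early mean -0.00706. With the highest-variance probe set Ubqln4 was 0.049, Tuba4a 0.15, Cd8a -0.052, Slc4a1 0.10 and the immediate early mean -0.0106.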

Other observations

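The tests on B cells, plasma cells, innate-like T cells, chromosome position and handling stress were chosen after part of the values they use had been seen, and the splits of the arrays were fixed beforehand. Most immunoglobulin probe sets were higher in the knockout: of 54 named ones 45 were, with a median difference of 0.48 over all 54. Without overlap between genotypes 32 were higher and 1 lower, where chance gives 10% and all probe sets of these arrays gave 17.2%. Several of the 54 name the same genes, so they are not independent. The 7 that rose past the threshold had a median rise of 2.09, and those of Ighm, the IgM heavy chain, differed by -0.06 to 3.78, the highest without overlap but not past the threshold (adjusted p = 0.0787). The 2 brightest of Ighm, at -0.04 and -0.02, averaged 13.7 and 14.3 in both genotypes, near the top of the measured range, where a change can be understated. The 3 probe sets of Igha rose by 1.81, 2.28 and 2.79. Another of the 7, an Ighg3 probe set, was dim, with a mean of 4.03 in the knockout and 2.87 in wild type. Plasma cell genes other than immunoglobulins were higher in 19 of 20 cases, among them Tnfrsf17, the survival receptor BCMA (1.15, SE 0.29), the secretory pathway genes Derl3 (0.82, SE 0.26) and Txndc5 (0.82, SE 0.19), and Sdc1, the surface marker CD138 (0.64, SE 0.22), although 0 passed over all genes and 4 of the 20 were also in the fixed lists.

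Transcripts associated with innate-like T cells went both ways. A probe set of Trgv4, a variable segment of the γδ T cell receptor, fell by 1.25 (SE 0.13), while the gene's brightest differed by -0.56 (adjusted p = 0.510), and Zbtb16, the factor that directs innate-like T cell development, differed by -1.51 (SE 0.28, adjusted p = 0.113). Tmem176a and Tmem176b, ion channel genes of RORγt-positive cells, differed by 0.68 (SE 0.17) and 0.81 (SE 0.20), with an adjusted p of 0.196 and 0.194. Of 23 measured genes of the innate-like list, written after some members had been seen, 8 were higher and 15 lower, 0 passed over all genes, and 9 were also in the fixed lists.

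For the 7 immunoglobulin probe sets that rose, more B cells in the knockout samples would raise B cell markers by a similar amount. The 14 markers without Jchain had a median of 0.019 (SD 0.48), below 1.04, which is 50% of the median rise of those 7. The 7 were picked by passing the threshold in these arrays, which favours a high bound, so it bears on those 7 alone. For all 54 probe sets the like bound is 0.24, within the SD of the markers, so more B cells stay open there. More plasma cells may contribute, by the same bars, which were set after the medians were seen. Their genes' median of 0.29 (SD 0.31) reaches 0.24 but not 1.04, and lies above the 95% range of random lists (-0.08 to 0.05). Camera gave p = 5.55e-09, and 0.0829 with an estimated correlation. The plasma cell list was written after part of its values had been seen, so these p-values are not independent support. It also keeps Jchain (0.58), which the B cell markers leave out, so the lists are not compared alike. Whether plasma cells account for the 7 cannot be told. Igha averaged 14.30 and Jchain 13.64 in the knockout, and Igha 12.49 and Jchain 13.06 in wild type, although a CD4 and CD25 separation would be thought to remove plasma cells. Of the 10 splits of the arrays 1, the real one, gave 7 immunoglobulin probe sets, and the highest other gave 0, which is too few splits for a share under 0.05. Whether the genotype alters plasma cells, the separation or Treg themselves, and whether immunoglobulin alleles differ between the animals, was not tested.

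For the genes that fell, alleles of another strain carried along with the Hdac6 locus are argued against by position, since 0 of the 13 genes that fell lay on chromosome X, and of the 20 genes with any probe set that fell 5% (1, Tceal8) did, with 0 within 50 measured genes of Hdac6. Alleles of another strain in several unlinked segments remain a candidate explanation. Outside the immunoglobulin and T cell receptor loci, the 13 genes that fell formed 4 pairs within 50 measured genes of each other. Random sets gave a median of 0 (one-sided permutation p = 0.00400). The 20 with any probe set that fell formed 5 against 1 (one-sided permutation p = 0.0202). With the genes that rose, the 28 genes with any changed probe set formed 7 against 3 (one-sided permutation p = 0.0334). The 28 include Sypl and Actb, whose brightest probe sets differed by 0.08 and -0.01. Sypl is also among the 20, where it pairs with Id2. The 18 genes that passed at the gene level formed 6 against 1 (one-sided permutation p = 0.00210). Pairs included Hal with Ntn4, Adh1 with Gbp2b, and Lclat1, which rose, with Ehd3. However, neighbouring genes can also be regulated together, and no genotypes were at hand. Fewer innate-like T cells cannot be told apart from these: the list's median of -0.11 lay below the 95% range of random lists (-0.07 to 0.07) as that explanation predicts, but camera, required beside it only after that median was seen, gave p = 0.377, or 0.704 with an estimated correlation. An effect of HDAC6 itself on these genes stays open and untested.

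For the higher Hspa1a and Hspa1b, which did not pass the threshold, handling stress is a technical explanation, because both were lowest in replicate 1 of each genotype, as were Fos and Jun. Within genotypes the immediate early genes rose by 0.16 (SE 0.02) per unit of Hspa1b, which predicted a genotype difference of 0.29, and the observed one was 0.02. The gap of -0.27 (SE 0.06, 3 residual degrees of freedom) argues against a handling stress that moves both kinds of gene with that slope. It does not argue against one that spares immediate early genes. The slope rests mainly on the replicate 1 arrays, and whether handling stress set these apart was not tested, so handling stress in general stays open. With the replicate number as a block the difference of 2.30 in Hspa1a had an adjusted p of 0.0404, where the alternatives ranged up to 0.730. A response of HSF1 targets to loss of HDAC6 stays open and was not tested apart from these arrays.

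For the counts, 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 44 probe sets against 1 in the highest other, 20 genes against 1, and 9 lists against 8. In each case 1 of the 10 splits, the real one, reached the real value. For lists the other splits gave 2 to 8, so the number of lists called hardly sets the genotypes apart from other groupings.

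Of the 64 control probe sets 0 passed the threshold when adjusted among themselves with limma, and the lowest adjusted p was 0.167 (difference -0.54).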
